A study of Mus musculus with 7 samples.

How the data were processed

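RNA was measured by sequencing in liver nonparenchymal cells, the cells of the liver other than hepatocytes, from mice of the C57BL/6 background at 2 months of age. The 7 libraries fall into 4 from wild-type (WT) mice and 3 from mice lacking Shp2 in Kupffer cells, the resident macrophages of the liver. Groups were taken from the sample titles. The genotype field of the 3 knockout libraries reads Shp1, Shp2 and Shp3 in turn while their titles all name Shp2, and the titles were followed. Libraries were made from total RNA with the TruSeq RNA v2 kit, per the labels' protocols, which does not mark the strand of the RNA.

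The authors deposited whole-number read counts per gene, not normalized, in 1 table of 20354 rows with a column per library. Reads were handled with FastQC 0.11.9, STAR 2.7.10a, SAMtools 1.9 and featureCounts 2.0.3 on GRCm39, per the submitters' processing notes. The annotation and the settings of these tools are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart, and reads shared by near-identical genes may have been dropped or split. Of the symbols, 20256 matched a current symbol in RefSeq's GRCm38.p6 gene table and 18 a synonym. That table was used for names and for which genes neighbour each other, and no coordinates are given because its build differs from that of the counts. Of the rows, 384 held no count in any library. Of the genes in the fixed lists, 10 had no row and were not analysed here.

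Counts summed to between 11678385 and 32003205 per library, so that 3 counts, the number a count of 0 can hide, correspond to between 0.0937 and 0.257 CPM, the count scaled to a common library total. The differences between libraries were far larger than counting noise (chi-square per degree of freedom of 38 to 294 over all pairs, within and between groups), so no library was a second copy of another. The labels number the libraries but do not say that each came from a separate mouse. The p-values measure the spread between these libraries.

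The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit with robust estimation and glmQLFTest) on the deposited counts, with TMM factors and the group as the only term. Genes were kept by filterByExpr (a minimum count of 10 and a minimum total of 15), which left 14077, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the test statistic. CPM values were scaled with the TMM factors, and log2 CPM used a prior count of 2. Gene lists were fixed for chemokine ligands, chemokine receptors, inflammatory cytokines, interferon-stimulated genes, interferon-gamma response and antigen presentation by MHC class II. Further lists covered ERK feedback and target genes, STAT feedback genes, alternative macrophage activation, phagocytosis and scavenger receptors, dissociation and stress genes, and cell cycle. Marker lists covered Kupffer cells, macrophages in general, monocytes and recruited macrophages, neutrophils, dendritic cells, T and NK cells, and B and plasma cells. They also covered sinusoidal endothelium, stellate cells and fibroblasts, cholangiocytes, hepatocytes, and erythroid cells and megakaryocytes. These 24 lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and a list of sex-linked genes was described only. A list score per library, the mean over members of log2 CPM centred on each gene's mean, was compared by a two-sided exact permutation test over the 35 ways of choosing 3 of 7 libraries, whose smallest possible p is 0.0286.

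Groups, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. The rule names Ptpn11, Ptpn6 and Clec4f, and then up to 10 genes in each direction among those past the threshold or, since none passed, the 10 with the smallest p among genes of at least 2 CPM whose groups did not overlap. It adds the 6 chemokine ligands and 6 receptors with the smallest p, and 2 members of every other list. Of the genes this rule names, 1 is not reported here. Other genes are named with a statement that they were chosen after their values were seen. Alternatives were DESeq2 1.42.0 (Wald test), limma voom without and with library quality weights, other scalings (DESeq2's size factors, upper quartile factors, library size only, and library sizes without hepatocyte, erythroid and mitochondrial genes), and no filter or a filter of 1 CPM in 3 libraries. Further alternatives were other thresholds, an estimated inter-gene correlation, fry, ranks in camera, and leaving out each library in turn. Leaving out 2 libraries together, WT replicate 2 and knockout replicate 3, was added after seeing the data. On simulated counts for this comparison (14012 genes, 4 against 3 libraries), edgeR found 29 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, with 7 false calls. DESeq2 found 56 and 100 of them with 39 false calls over 14077 genes, and limma voom 27 and 96 with 9 false calls over 14012 genes. The changed genes were taken from those with higher counts. Each gene was drawn independently, so libraries standing apart, such as WT replicate 2 and knockout replicate 3, were not reproduced. The rates may therefore not hold for the real libraries. With no list shifted camera called 0 of the simulated lists, and it called the 1 list shifted 1.5-fold. Because members of a list were simulated independently, this does not show how often camera calls lists whose genes move together. In the real libraries the estimated inter-gene correlation reached 0.797, in the sinusoidal endothelial markers.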

Results

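Nonparenchymal cells were isolated from the livers of WT mice (n = 4 libraries) and of mice in which Cre recombinase under Clec4f, a gene of resident Kupffer cells, deletes Ptpn11, the gene of the tyrosine phosphatase Shp2 (n = 3). The comparison asks how losing Shp2 in Kupffer cells alters gene expression, chemokine genes first, in the whole nonparenchymal fraction. Total counts were 16721435, 19208217, 11678385 and 26545605 in the WT libraries. They were 32003205, 19383142 and 15263666 in the knockout libraries. Mitochondrial genes took 17.3% to 22.4% of the counts in WT libraries, and 20.9%, 33.2% and 18.1% in knockout replicates 1 to 3. The ribosomal RNA gene Rn18s took 7.54% of the counts in knockout replicate 3 and between 0.0527% and 0.122% in each other library. WT replicate 2 and knockout replicate 3 stood apart from the remaining libraries on the first 2 principal components, which held 33.9% and 27.5% of the variance. Albumin, a hepatocyte product, took 2.64% ± 1.02 (SD, n = 4) of WT counts and 2.29% ± 1.01 (SD, n = 3) of knockout counts (exact permutation test, p = 0.657).

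Ptpn11 itself was measured at 75.3, 95.5, 80.7 and 82.9 CPM in the WT libraries and at 70.0, 79.5 and 86.2 CPM in the knockout libraries. Its log2 fold change was -0.09 ± 0.18 (SE; edgeR quasi-likelihood test, adjusted p = 0.974). Kupffer cells are one of several cell types in the fraction and a gene count includes exons outside any deleted part, so this value is a weak check of the genotype. Ptpn6, the gene of the related phosphatase Shp1, had a log2 fold change of 0.20 ± 0.23 (SE; edgeR, adjusted p = 0.956), which turned to -0.09 without knockout replicate 3. Clec4f, whose promoter drives the Cre, was at 1892 ± 549 CPM (SD, n = 4) in WT and 585 ± 243 CPM (SD, n = 3) in knockout libraries, and each knockout library lay below every WT library.

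Several genes of resident Kupffer cells had lower values in the knockout fraction, while Cd207 and Cx3cr1 had higher ones. The haemoglobin scavenger receptor Cd163 was at 346 ± 168 CPM (SD, n = 4) in WT and 32.7 ± 17.9 CPM (SD, n = 3) in knockout libraries, a log2 fold change of -3.41 ± 0.47 (SE). Cd207, which encodes the lectin langerin, was at 89.8 ± 23.6 CPM against 366 ± 28.3 CPM (SD), a log2 fold change of 2.03 ± 0.25 (SE). The transcription factor gene Zbtb16 (-2.29 ± 0.35), the lipid receptor gene Gpr55 (-2.34 ± 0.39), Tmem100 (-2.03 ± 0.31), Ccdc148 (-1.85 ± 0.31), the phospholipase gene Pla2g7 (-1.15 ± 0.22) and the immunoglobulin gene Ighg2b (-2.19 ± 0.40, whose reads may be shared with related constant genes) had lower log2 values (± SE). The fractalkine receptor gene Cx3cr1 was higher (1.92 ± 0.32). In each of these genes the groups did not overlap, which the rule for naming them required.

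None of the 14077 genes passed the adjusted threshold in edgeR's quasi-likelihood test: 0 were called, and the smallest adjusted p was 0.117 (Cd207). In the same test 650 genes had an unadjusted p under 0.05, 319 higher and 331 lower, where 704 would be reached by chance. DESeq2 called 65 genes, 10 higher and 55 lower, with 858 at unadjusted p under 0.05. Limma voom called 0, with 636 at unadjusted p under 0.05, and voom with library quality weights called 9, 3 higher and 6 lower. Without WT replicate 2 and knockout replicate 3 together, a choice made after seeing the data, edgeR called 2 genes, Cd163 and Galnt15, both lower. Galnt15 was named after its value was seen. The groups did not overlap in 855 genes, or 6.07% of those tested, where chance gives 5.71%.

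**Figure D1:**
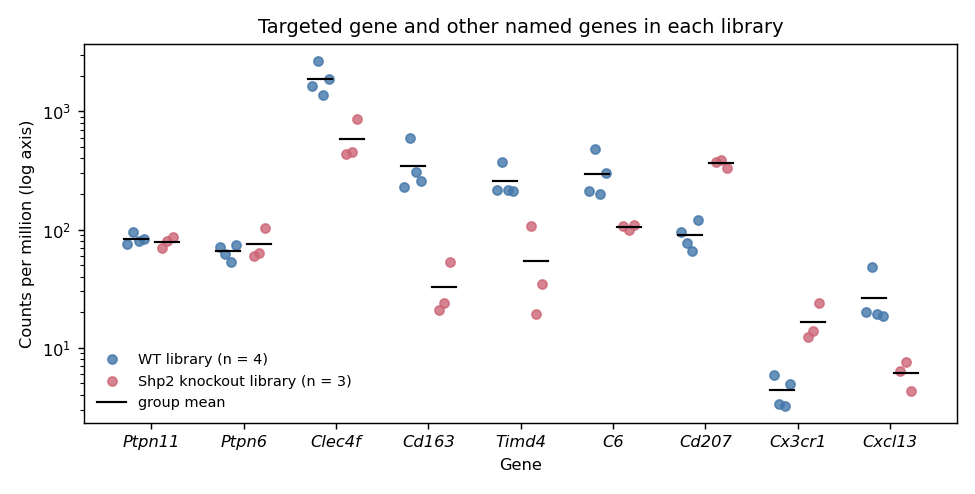
CPM on a log axis for 9 named genes, with a point for each WT library (n = 4) and each Shp2 knockout library (n = 3) and a bar at each group mean. Ptpn11 lies between 70.0 and 95.5 CPM in both groups, while the Clec4f, Cd163, Timd4, C6 and Cxcl13 points of the knockout lie below, and those of Cd207 and Cx3cr1 above, all WT points.

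Among chemokine ligands, the clearest difference was in Cxcl13, which attracts B cells. It was at 26.6 ± 14.5 CPM (SD, n = 4) in WT and 6.08 ± 1.64 CPM (SD, n = 3) in knockout libraries, a log2 fold change of -2.13 ± 0.40 (SE). WT replicate 2 stood at 48.3 CPM and the other WT libraries between 18.5 and 20.1 CPM. Cxcl13 fell when adjusted over the list alone (edgeR, adjusted p = 0.00833), but not over all genes (adjusted p = 0.360). Ccl6 (-0.91 ± 0.30), the eosinophil attractant Ccl24 (-0.56 ± 0.20) and the low-count Cx3cl1 (-1.90 ± 0.58) had negative log2 fold changes (± SE). Ccl12 (2.00 ± 0.64) and Ccl3 (1.49 ± 0.51), both under 2 CPM in every library, had positive ones. Of 29 ligands tested, edgeR called 0 over all genes and 1 adjusted over the list alone. At unadjusted p under 0.05 there were 9, 5 higher and 4 lower, but 2 higher and 6 lower without WT replicate 2 or without knockout replicate 2. DESeq2 and voom with quality weights each called 1 over all genes, Cxcl13, and voom without weights called 0. As a group the ligands had a median log2 fold change of 0.09 and were not shifted in a single direction (camera, adjusted p = 0.672). Fry's test for changes in either direction passed the list (adjusted p = 0.0243), while its test for a single direction did not (adjusted p = 0.958). The median was 0.415 without WT replicate 1, -0.043 without WT replicate 4 and -0.034 without knockout replicate 2. Adjusted over the list alone, 5 ligands passed without WT replicate 1, 3 without WT replicate 4 and 2 without knockout replicate 3, Cxcl13 among them each time.

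Among chemokine receptors, Cx3cr1 rose when adjusted over the list alone, from 4.36 ± 1.27 CPM (SD, n = 4) in WT to 16.6 ± 6.34 CPM (SD, n = 3) in knockout libraries (edgeR, unadjusted p = 0.000114, adjusted p over all genes = 0.267). Ccr3 (1.13 ± 0.37), Ccr1 (0.71 ± 0.34) and the neutrophil receptor gene Cxcr2 (0.74 ± 0.57) had positive log2 fold changes (± SE), and Cxcr4 (-0.44 ± 0.19) and Ccrl2 (-0.64 ± 0.35) negative ones. Of 20 receptors tested, edgeR called 0 over all genes and 1 adjusted over the list alone, with 3 at unadjusted p under 0.05. DESeq2 and voom with quality weights each called 1, Cx3cr1, and voom without weights called 0. The group was not shifted (median log2 fold change 0.10, camera, adjusted p = 0.573).

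**Figure D2:**
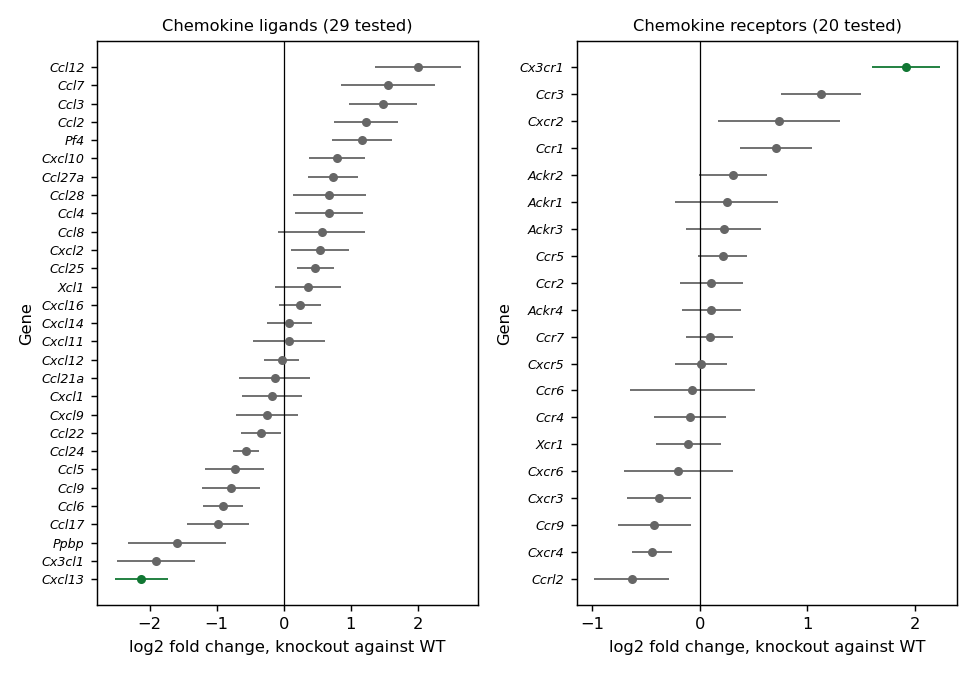
Log2 fold change of knockout against WT libraries for the 29 chemokine ligands and 20 chemokine receptors tested, with bars of 1 SE. Green marks the genes past the threshold when adjusted over the list alone, Cxcl13 at -2.13 and Cx3cr1 at 1.92.

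Kupffer cell markers fell as a group (camera with a preset correlation, adjusted p = 6e-07), but the p was 0.398 with an estimated correlation. Of 16 tested, 12 were below 0, and 6 passed when adjusted over the list alone, all lower, with 8 at unadjusted p under 0.05 and 0 over all genes in edgeR. They were Cd163, Timd4, a receptor for dying cells (-2.24 ± 0.53, SE), Clec4f (-1.69 ± 0.39), the complement gene C6 (-1.50 ± 0.33), Vsig4 and Folr2, the last pair named after their values were seen. DESeq2 called 4 over all genes, Cd163, Timd4, Clec4f and C6. The members did not move alike: Cd5l and Slc40a1, also named after their values were seen, had log2 fold changes of -0.20 and -0.08. Adjusted over the list alone, 4 markers passed without WT replicate 4, and 4 without knockout replicate 1 or 2. The 8 markers at unadjusted p under 0.05 became 4 without knockout replicate 2, and 7 or 8 without any other library. The list score was 0.31 ± 0.34 (SD, n = 4) in WT and -0.41 ± 0.31 (SD, n = 3) in knockout libraries (exact permutation test, p = 0.0286, the smallest possible; adjusted p = 0.229), and WT replicate 2 held the highest score at 0.80.

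Phagocytosis and scavenger receptors fell as a group (camera, adjusted p = 6.38e-05; adjusted p = 0.433 with an estimated correlation). Of 19 tested, 4 passed adjusted over the list alone, all lower (Cd163, Timd4, Colec12 and Fcgr3). In edgeR 5 were lower at unadjusted p under 0.05. Adjusted over the list alone, 2 passed without WT replicate 3, WT replicate 4 or knockout replicate 2 (Cd163 and Timd4 each time), and 1 without knockout replicate 3 (Cd163). WT replicate 2, rich in endothelial transcripts, held a list score of 0.77 against -0.003 to 0.07 in the other WT libraries. Genes of alternative macrophage activation fell as a group (camera, adjusted p = 0.000899; adjusted p = 0.238 with an estimated correlation), with 1 of 13 adjusted over the list alone, Cd163. Ccl24 was at -0.56 and also passed over the list alone without knockout replicate 3 (2 genes). Markers of monocytes and recruited macrophages rose as a group (camera, adjusted p = 0.0249; adjusted p = 0.398 with an estimated correlation), with 1 of 14 adjusted over the list alone, Cx3cr1. Plac8 was at 0.84 ± 0.37 (SE). That call was lost with camera on ranks (adjusted p = 0.0691), without WT replicate 2 (adjusted p = 0.167) and without knockout replicate 2 (adjusted p = 0.293). General macrophage markers were not shifted (median log2 fold change -0.25, camera, adjusted p = 0.672). In edgeR 0 of 15 passed adjusted over the list alone, with 1 at unadjusted p under 0.05, Ms4a7 (1.10 ± 0.31, SE), and Aif1 at 0.35. Ms4a7 passed over the list alone without knockout replicate 3 (1 gene).

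Cell cycle genes rose as a group (camera, adjusted p = 5.85e-08; adjusted p = 0.238 with an estimated correlation). Of 24 tested, 23 were above 0 with a median log2 fold change of 0.40, and 0 passed in edgeR adjusted over the list alone. At unadjusted p under 0.05, 5 were higher, among them the mitotic genes Cenpe (0.91 ± 0.27, SE) and Ube2c (1.00 ± 0.33, SE). Without knockout replicate 2 that count was 2, and without any other library 4 or 5. Interferon-stimulated genes rose as a group (camera, adjusted p = 3.14e-07, or adjusted p = 0.398 with an estimated correlation), with 19 of 20 above 0 and a median of 0.44. Without 1 library the median lay between 0.26 (knockout replicate 3 left out) and 0.584 (knockout replicate 1 left out). Within this list, edgeR passed 0 adjusted over the list alone, and 6 were higher at unadjusted p under 0.05, among them Mx1 (0.86 ± 0.25, SE) and Isg15 (0.98 ± 0.30, SE). That count was 3 without WT replicate 1, WT replicate 3, WT replicate 4 or knockout replicate 3, and 4 without knockout replicate 2. It was 10 without knockout replicate 1 and 11 without WT replicate 2. Adjusted over the list alone, 7 passed without knockout replicate 1 and 2 without WT replicate 2, all higher. Knockout replicate 1 had a list score of -0.11, inside the WT range of -0.40 to 0.13. DESeq2 and voom with quality weights called 0 members of either list over all genes. Adjusted over the list alone, DESeq2 passed Isg15 and Mx1 (2 genes), and voom with quality weights 6 interferon-stimulated and 2 cell cycle genes (Cenpe and Birc5, the latter named after its value was seen), all higher. Inflammatory cytokines rose as a group (camera, adjusted p = 0.0249; adjusted p = 0.433 with an estimated correlation), with 0 of 18 adjusted over the list alone. In edgeR 1 member had an unadjusted p under 0.05, Il6 at 0.97 ± 0.36 (SE), and Il15 was at 0.44. That call was lost without WT replicate 3 (adjusted p = 0.0634), WT replicate 4 (0.230), knockout replicate 1 (0.0512) or knockout replicate 2 (0.293).

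The interferon-gamma response was not shifted (camera, adjusted p = 0.0683, median 0.26), with 0 of 16 adjusted over the list alone and 0 at unadjusted p under 0.05. Gbp4 was at 0.63 and Gbp3 at 0.38. It passed with camera on ranks (adjusted p = 0.0365) and without WT replicate 1 (adjusted p = 0.00345) or knockout replicate 1 (0.00122) and turned downward without knockout replicate 2 (0.847). MHC class II antigen presentation was not shifted (camera, adjusted p = 0.784), with 0 of 14 adjusted over the list alone and 3 at unadjusted p under 0.05. The costimulatory gene Cd40 was at 1.06 ± 0.33 (SE) and Ciita at 0.62, and Cd40 passed over the list alone without WT replicate 1 (1 gene). ERK feedback and target genes, which follow a pathway Shp2 acts in, were not shifted (camera, adjusted p = 0.784, median 0.04), with 0 of 16 adjusted over the list alone and 0 at unadjusted p under 0.05. Etv1 was at -0.39 and Myc at 0.31. The counts come from the whole fraction, so a change of ERK target genes limited to Kupffer cells could be missed. STAT feedback genes were not shifted (camera, adjusted p = 0.784, median 0.03), with 0 of 10 adjusted over the list alone and 1 at unadjusted p under 0.05. This was Bcl6 (-0.93 ± 0.29, SE), and Bcl3 was at 0.68. Bcl6 passed over the list alone without WT replicate 1 (1 gene). Dissociation and stress genes were not shifted (camera, adjusted p = 0.140), with 0 of 18 adjusted over the list alone and 0 at unadjusted p under 0.05. Dusp1 was at -0.61 and Junb at 0.88, and the list passed without WT replicate 4 (adjusted p = 0.0151). Over all genes DESeq2 called 0 members of these 5 lists.

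T and NK cell markers fell as a group only in camera with the preset correlation (adjusted p = 8.35e-05). With the estimated correlation of 0.668 camera did not call these markers (adjusted p = 0.605). Of these, 17 of 19 were below 0, with 0 adjusted over the list alone in edgeR, 3 lower at unadjusted p under 0.05 and 0 called by DESeq2. Klrb1c was at -0.88 ± 0.33 and the perforin gene Prf1 at -0.70 ± 0.29 (log2, SE), and the camera call was lost without knockout replicate 3 (adjusted p = 0.257). The T and NK list scores overlapped, at -0.525 to 0.658 in WT and -0.78 to 0.234 in knockout libraries (exact permutation test, p = 0.343). Cholangiocyte markers rose as a group (camera, adjusted p = 0.00476; adjusted p = 0.398 with an estimated correlation), all 8 above 0, with 0 adjusted over the list alone, 0 at unadjusted p under 0.05 in edgeR and 0 called by DESeq2. Cldn7, under 1 CPM, was at 0.88 and Spp1 at 0.51, and the call was lost without WT replicate 2 (adjusted p = 0.0669). Stellate cell and fibroblast markers were not shifted (camera, adjusted p = 0.0683), with 0 of 16 adjusted over the list alone and 2 higher at unadjusted p under 0.05. These were Col3a1 (0.59 ± 0.20, SE) and Ngfr (0.93 ± 0.33, SE), and the list passed without WT replicate 1 (adjusted p = 0.0158). Without knockout replicate 3, 1 gene passed over the list alone, Lrat, named after its value was seen.

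Sinusoidal endothelial markers were not shifted (camera, adjusted p = 0.417), with 0 of 16 adjusted over the list alone and 0 at unadjusted p under 0.05. Lyve1 was at -0.84 and Plpp3 at -0.72, and WT replicate 2 held a list score of 1.00 against -0.43 to -0.06 in the other WT libraries. Without it the list passed in the upward direction (adjusted p = 0.0307), and without WT replicate 4 in the downward direction (adjusted p = 0.0290). Hepatocyte markers were not shifted (camera, adjusted p = 0.0557, median -0.19), with 0 of 20 adjusted over the list alone and 1 at unadjusted p under 0.05. This was Tat (-1.97 ± 0.57, SE), which DESeq2 called, and Cps1 was at -0.77. Tat passed over the list alone without WT replicate 1 (1 gene). As a group the markers passed without WT replicate 1 (adjusted p = 0.000149), WT replicate 2 (0.00623), knockout replicate 1 (0.00808) or knockout replicate 2 (0.0398), and turned upward without WT replicate 4 (0.670).

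Neutrophil markers differed in sign between measures: camera's direction was downward (adjusted p = 0.992), while the median was 0.41 and the mean 0.11. Of 12 tested, 2 passed adjusted over the list alone, both lower, the granule genes Ltf (-1.69 ± 0.45, SE) and Ngp (-2.04 ± 0.55, SE), both under 4 CPM, while at unadjusted p under 0.05 there were 3 higher and 3 lower. Adjusted over the list alone, 0 passed without WT replicate 2 or knockout replicate 2, 1 (lower) without knockout replicate 1, 3 (1 higher, 2 lower) without WT replicate 4 and 8 (6 higher, 2 lower) without knockout replicate 3. Dendritic cell markers (camera downward, adjusted p = 0.784, median 0.08) had 0 of 14 adjusted over the list alone and 2 at unadjusted p under 0.05. Batf3 was at 1.55 and Klk1 at -0.89. B and plasma cell markers (camera downward, adjusted p = 0.663) had a median of 0.11 and a mean of -0.12. Of 15 tested, 1 passed adjusted over the list alone, the antibody light chain gene Igkc (-1.42 ± 0.36, SE), and the list passed without knockout replicate 1 (adjusted p = 0.0275). Igkc passed over the list alone with all libraries and without WT replicate 3, and 0 genes passed without any other library. Erythroid and megakaryocyte markers (camera upward, adjusted p = 0.784, median -0.12) had 0 of 8 adjusted over the list alone and 1 at unadjusted p under 0.05. Pf4 was at 1.18 and Ppbp at -1.59, and Pf4 passed over the list alone without WT replicate 4 (1 gene). Of the sex-linked genes, Ddx3y (-0.18) and Eif2s3y (0.24) were detected in all 7 libraries, and Xist had at most 11 counts in a library.

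With an estimated correlation or with fry's test for a single direction, 0 of the 24 lists passed after adjustment. Camera with the preset correlation called 9, 5 upward and 4 downward. With list scores compared by exact permutation 0 passed too, but there a list can pass only if most lists reach the smallest possible p, 0.0286. It was reached by the scores of Kupffer cell markers, cell cycle genes and alternative macrophage activation, each with an adjusted p of 0.229. Kupffer cell markers and cell cycle genes passed fry's test for changes in either direction (adjusted p = 0.0234 each). Chemokine ligands (fry, adjusted p = 0.0243) and phagocytosis and scavenger receptors (fry, adjusted p = 0.0486) passed it as well. Over all genes, edgeR's quasi-likelihood test called 0 members of any list. DESeq2 called 2 of the phagocytosis and scavenger receptors, 1 gene each of alternative activation, recruited macrophages and B and plasma cells, and 0 of the general macrophage, neutrophil, dendritic, endothelial, stellate and erythroid lists. Adjusted over each list alone, voom with quality weights passed 0 B and plasma cell markers but more genes than edgeR in other lists: 7 chemokine ligands, 5 receptors, 8 Kupffer cell markers, 8 neutrophil markers (5 higher, 3 lower), 4 of alternative activation, 3 stellate cell markers, 2 each of MHC class II, STAT feedback and T and NK cell markers, and 1 each of the general macrophage and cholangiocyte lists. DESeq2 passed 3 ligands, 7 Kupffer cell markers, 5 scavenger receptors, and 1 each of the MHC class II, STAT feedback, general macrophage, dendritic and hepatocyte lists.

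**Figure D3:**
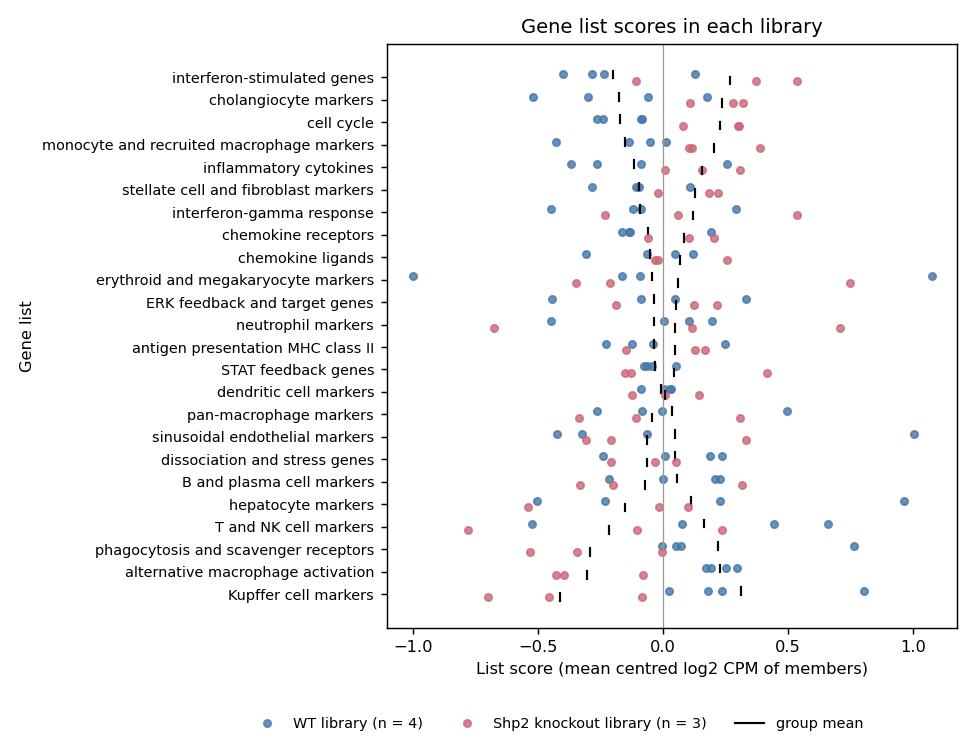
List score of 24 gene lists in each library, the mean over members of log2 CPM centred on each gene's mean, with a point per WT (n = 4) and Shp2 knockout (n = 3) library and a bar at each group mean. For Kupffer cell markers the knockout libraries lie between -0.70 and -0.08 and the WT libraries between 0.02 and 0.80.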

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

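The 4 tests on Kupffer cell markers were chosen after the result was seen, and the counts over other splits of the libraries were planned. The test on the Cre allele is the fourth version tried: the first, on Cd163, Timd4 and C6, picked for their fall, and the second, on the mean score alone, argued against that explanation, and the third, adjusted over the lists, could hardly have passed. The 8 values given first come from a rule for 1 sample far from the rest of its group, applied to the WT group only because the knockout group has 3 libraries. It was applied to 93 measures, where chance gives about 4.7, and 5 of the 8 lie in WT replicate 2.

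In WT replicate 2, Cxcl13 stood at 5.60 log2 CPM against 4.22 to 4.33 in the other WT libraries. Timd4 stood at 8.56 against 7.74 to 7.76, and Plpp3 at 10.39 against 8.66 to 8.80. Ccr1 was low there, at 2.22 against 3.20 to 3.38, and the score of phagocytosis and scavenger receptors was 0.77 against -0.003 to 0.07. In WT replicate 1, Ccl6 was low at 7.97 log2 CPM against 8.89 to 8.99, Cps1 was low at 9.36 against 10.24 to 10.40, and the chemokine receptor score was 0.19 against -0.16 to -0.13.

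Because edgeR called 0 genes for the genotypes, all 35 splits of the 7 libraries into 4 and 3 reach that count by construction, which says nothing about chance; the highest other split gave 2. For the other counts chance could not be excluded. For genes at unadjusted p under 0.05, 14 of the 35 splits gave as many as the 650 of the genotypes, and the highest other gave 2549. For DESeq2, 5 of the 35 gave at least 65 calls, with 636 as the highest other. For camera, 11 of the 35 gave at least 9 lists, with 13 as the highest other. The split with 2549 genes and 636 DESeq2 calls set WT replicates 1 and 2 and knockout replicate 3 against the rest, which points to a structure of the samples that the genotypes do not follow.

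Among the Kupffer cell markers, Clec4f, Cd163, Timd4 and C6 were the lowest in the knockout fraction. For Clec4f and the other markers together, a lower share of Kupffer cells as the only cause is argued against under an assumption. The assumption is that all these markers come from Kupffer cells alone, which a mixed fraction cannot show. The 15 markers other than Clec4f, with Cd163, Timd4 and C6 among them, had a median log2 fold change of -0.20 (interquartile range 0.88) against -1.69 for Clec4f. If the Cre allele itself lowers Clec4f, this gap does not test a lower share for these 15, which then stays open. An effect of the Cre allele on its own locus alone is not excluded by these 15 as a set: their score was lower by 0.66 (exact permutation test, p = 0.0286) as a mean over the markers, but as a median, on which a few markers weigh less, it did not pass (p = 0.0857). For Clec4f and Cd207, which lie next to each other in the gene order, such an effect and Shp2 loss cannot be told apart, because every knockout library carries the allele: 0 of the 6 other nearest tested genes had an unadjusted p under 0.05, and an allele could act on 1 neighbour alone. Recruited macrophages taking the place of resident cells, which may share many of the markers that did not move, also stay open (score difference 0.35, exact permutation test, p = 0.0571), as does an effect of Shp2 loss on these genes.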

How the results depend on the processing

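Leaving out WT replicate 2 and knockout replicate 3 together was chosen after seeing the data, and every other alternative was planned. The count of changed genes, 0 in edgeR, became 3 with library size only, 3 with no filter on low counts, 65 with DESeq2, 9 with voom with quality weights and 2 with both outlying libraries left out, and was 0 without each library in turn. For chemokine ligands and for receptors the count of 0 became 1 with DESeq2, 1 with voom with quality weights and 1 adjusted over the list alone. The 9 gene lists called became 0 with an estimated correlation and 0 with fry's test for a single direction. They became 0 with list scores, where the smallest possible p leaves hardly any list able to pass. Without each library in turn the count was 8 to 12. Ptpn11 stayed below 0 under every alternative, from -0.16 to -0.02 without each library in turn. Why the counts differ was not separated further, and the cause was not tested.

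Over 63 named genes and 17 alternatives, 1031 of 1062 values kept their direction and their side of the threshold, 29 newly passed it, 15 of these with DESeq2, and 2 turned in direction, both of the gene Ptpn6, at -0.088 without knockout replicate 3 (-0.088 to 0.333 without each library in turn) and -0.116 with both outlying libraries left out. With at least 1 CPM in 3 libraries 57 of the 63 genes were tested, and Ccl3 was not tested without WT replicate 2, WT replicate 4 or knockout replicate 2. Over 24 lists and 13 alternatives, 232 of 312 values were the same, 36 lost the call, 11 gained it and 33 turned in direction. Without 1 library the number of turns, with the range of adjusted p over the 7 libraries left out, was: chemokine ligands 2 (0.331 to 0.953), interferon-gamma response 1 (0.00122 to 0.847), antigen presentation MHC class II 4 (0.197 to 0.981), ERK feedback and target genes 2 (0.194 to 0.956), STAT feedback genes 1 (0.45 to 0.953), pan-macrophage markers 2 (0.111 to 0.767). For the others it was: neutrophil markers 2 (0.102 to 0.981), dendritic cell markers 1 (0.392 to 0.981), B and plasma cell markers 3 (0.0275 to 0.965), sinusoidal endothelial markers 1 (0.029 to 0.982), hepatocyte markers 1 (0.000149 to 0.831), erythroid and megakaryocyte markers 2 (0.134 to 0.965). With both outlying libraries left out they were MHC class II 0.717, STAT genes 0.245, neutrophil markers 0.108, dendritic cell markers 0.341, endothelial markers 0.83 and erythroid markers 0.115. Neutrophil markers also turned with fry (0.960), list scores (0.954), DESeq2's size factors (0.939) and ranks (0.623), and dendritic cell markers with list scores (0.971). The cause of these was not tested. The median log2 fold change of all genes stayed between -0.03 and 0.05 under every alternative.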

Other observations

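The gene groups described here were noticed in the data, so the tests on them were chosen after the result was seen, except the tests on glucocorticoid targets and on plasma cell genes whose values had not been viewed when the lists were written. The comparison for hepatocytes was first made with targets chosen for low values, where it argued against a lower share, and was replaced because that choice sets their median.

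Immunoglobulin genes were lower in the knockout fraction. Of 88 tested, 85 had a log2 fold change below 0, 51 were lower at unadjusted p under 0.05 and 0 higher in edgeR, and the median was -1.39. Their list score was between 0.07 and 1.05 in WT and between -1.13 and -0.21 in knockout libraries (exact permutation test, p = 0.0286, the smallest possible). Immunoglobulin segments resemble each other and can share reads, so the genes are not independent and single values are uncertain. Some genes known as targets of glucocorticoid hormones were noticed for their low values, among them Cd163 at -3.41 ± 0.47 (SE), Zbtb16 at -2.29 ± 0.35 (SE), Fkbp5, a feedback gene of the glucocorticoid receptor, at -2.07 ± 0.43 (SE), Tsc22d3 at -0.98 ± 0.30 (SE) and Fam107a at -4.58 ± 0.87 (SE). The score of 16 targets chosen for such values did not pass (exact permutation test, p = 0.0571).

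For the glucocorticoid targets no explanation was argued against. Cd163, also in the lists of Kupffer cell markers, scavenger receptors and alternative activation, is a macrophage gene, so a lower share of hepatocytes would not bear on it. Lower glucocorticoid signalling in the knockout mice may contribute: 16 further targets, not viewed when listed, had a median log2 fold change of -0.78, 15 of them below 0, but the score difference of -0.82 did not pass (exact permutation test, p = 0.114), because WT replicate 1 at -0.27 lay among the knockout libraries. A lower share of hepatocytes stays open. The median of the hepatocyte markers, -0.19, differed from that of the further targets by 0.60, less than the markers' interquartile range of 0.68. It differed by 0.87 from the -1.06 of the targets chosen for low values. The hepatocyte markers include Tat (-1.97) and Pck1 (-1.14), which are also among those chosen targets. Both widen the markers' range, so this comparison cannot decide. Another hour of collection could also shift such genes, and the clock genes leave it open. The score difference was 0.074 for the evening arm (p = 0.571, exact permutation test) and -0.25 for the morning arm (p = 0.0571, same test). The morning arm has 3 tested genes and rests on Cry1 at -0.96. Members of the evening arm moved in both directions, which its mean does not show. Of 7 tested, 2 were higher (Nr1d1 at 1.05 and Dbp at 0.62) and 1 lower (Per2 at -0.72) at unadjusted p under 0.05 in edgeR. These genes were named after their values were seen.

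For the immunoglobulin genes, a lower share of B cells is argued against by B cell genes, whose median log2 fold change was 0.16 (interquartile range 0.21). A lower share of plasma cells may account for part of it, but 10 plasma cell genes not viewed beforehand had a score difference of -0.11 (exact permutation test, p = 0.543), which leaves it open. In the fixed B and plasma cell list, Jchain was at -1.28 ± 0.58 and Tnfrsf17, with low counts, at -0.915 ± 0.47 (log2, SE). Xbp1 of the same list was at -0.07. None of them had an unadjusted p under 0.05 in edgeR, and they were named after their values were seen. No test separated an effect of Shp2 loss in Kupffer cells from other differences between these mice.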
